A study of Mus musculus with 16 samples.

How the data were processed

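RNA from whole brown adipose tissue of C57BL6/N mice was measured at 5 ages on 16 Agilent 1-colour arrays, 8 on each of 2 slides. Total RNA was extracted with ISOGEN and labelled with Cy3, per the labels. The intensity values used are the processed signals of the scanner files, which per the file headers are background subtracted and spatially detrended for each array and not normalized between arrays. The file headers name Agilent Feature Extraction 11.5.1.1, and the submitters' processing notes name version 11.0.1.1. The deposited series matrix holds log2 values: tested on the files, its sorted columns differ by 0 and its ranks differ from those of the processed signal by at most 1, so it is the log2 processed signal after quantile normalization between arrays. How the submitters made it is not given in the sources used here. It served only as an alternative.

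Each array holds 62976 spots. The 3671 control spots were left out, and 2720 spot values marked non-uniform or as population outliers over all arrays were set to missing. No non-control spot was saturated. Spots of one probe were averaged, which gave 55681 probes. RefSeq accessions of the array were joined to symbols, and 27656 probes had a symbol, for 20972 symbols. The 28025 probes without one entered no gene result. The probe annotation of the array design is on mm9, per the file headers. Signals were taken as log2 minus the 75th percentile of the array. A probe was kept when well above background on at least 3 arrays, and a gene was measured by its kept probe with the highest mean over all arrays, which left 16436 genes. Of 4202 genes with several kept probes, those with probes past the test in both directions numbered 179 for P4 versus E18, 100 for P10 versus P4, 160 for 4W versus P10, 107 for 8W versus 4W and 266 for 8W versus E18.

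Samples were grouped by the age in the labels. All arrays entered one limma fit (limma 3.58.1, R 4.3.3) with age as the only term. A moderated F test asked for any difference between the ages, and moderated tests compared P4 with E18, P10 with P4, 4W with P10, 8W with 4W and 8W with E18. All tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 44 lists with at least 5 measured genes. The comparisons, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined.

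The text names a fixed panel of genes, members of the lists past camera with the largest changes among genes whose arrays do not overlap, and the 5 genes that rose and the 5 that fell most. Members of lists beyond the first 7 of a comparison were chosen after their values were seen. A gene that this rule would allow is not reported here. Alternatives were quantile and median scaling, normexp background correction with an offset of 50, the series matrix, no filter on dim probes, only probes above background on all arrays, marked spots kept, the mean of a gene's probes, slide as a block, the arrays of 1 slide, a replicate block, only the arrays of the ages compared, a trended robust prior, array weights, an estimated correlation for the lists and each array left out in turn. The normexp correction used the median pixel of each spot, since the mean was not in the columns used here. Further settings, chosen after seeing the data, left out the P10 arrays, the genes that follow muscle markers, or the P4 and P10 arrays that lie on the other slide than the rest of their age.

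The limma fit and the list test were run on simulated values, drawn from the mean and spread of each gene after scaling and filtering. In simulated values for P4 versus E18, of 50 genes changed at each size the fit recovered 12 at a log2 change of 0.25, 24 at 0.5, 40 at 1 and 47 at 2, and called 8 unchanged genes (6.11% of calls). In those for 8W versus 4W it recovered 8, 28, 39 and 44, and called 5 unchanged genes (4.03% of calls). No list without a change was called in either. The genes were simulated as independent, so this could not show false list calls that arise when the genes of a list vary together. Scaling, background correction, the filter on dim probes and the choice of probes were not part of the simulation. Far fewer genes were changed in it than passed in the data, so its shares need not hold there.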

Results

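Brown adipose tissue, the fat depot that burns lipid to produce heat, was sampled whole from C57BL6/N mice at embryonic day 18 (E18), at postnatal days 4 (P4) and 10 (P10) and at 4 and 8 weeks of age (4W and 8W). Total RNA labelled with Cy3 was hybridised to 16 Agilent 1-colour arrays, 4 at P4 and 3 at each other age. The 75th percentile of the processed signal lay between 351 and 753 intensity units per array, and the number of arrays limits the precision. On average 67.0% ± 0.13 (SD, n = 3) of probes were well above background at E18, 54.9% ± 3.26 (n = 4) at P4, 64.5% ± 6.57 (n = 3) at P10, 49.8% ± 3.17 (n = 3) at 4W and 47.1% ± 2.78 (n = 3) at 8W. The series follows how the transcriptome of this tissue changes over its development, so each age was compared with the one before it and the last with the first. Below, folds come from the limma fit over 16436 genes, ± is the standard error (SE) of the log2 change, and n is 4 arrays at P4 and 3 at every other age.

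The brown fat transcriptome differed between the ages at most genes. By limma's F test 13830 of the 16436 genes (84.1%) changed between the 5 ages, and for 6771 of these the age means spanned at least a 2-fold range. Of those 6771 genes, 1825 had their highest mean at E18, 1505 at P4, 919 at P10, 1110 at 4W and 1412 at 8W. Scaling by the array median instead placed 1205 genes at E18 and 2139 at 4W. In a fit with a slide term 13242 genes passed the F test. The labels do not say whether the arrays of an age are separate animals, and the median SD of a gene within an age was 0.038 to 0.10 (log2), against 0.063 to 0.095 between copies of one probe on one array. The p-values therefore measure only the spread between these samples, which may be technical.

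**Figure D1:**
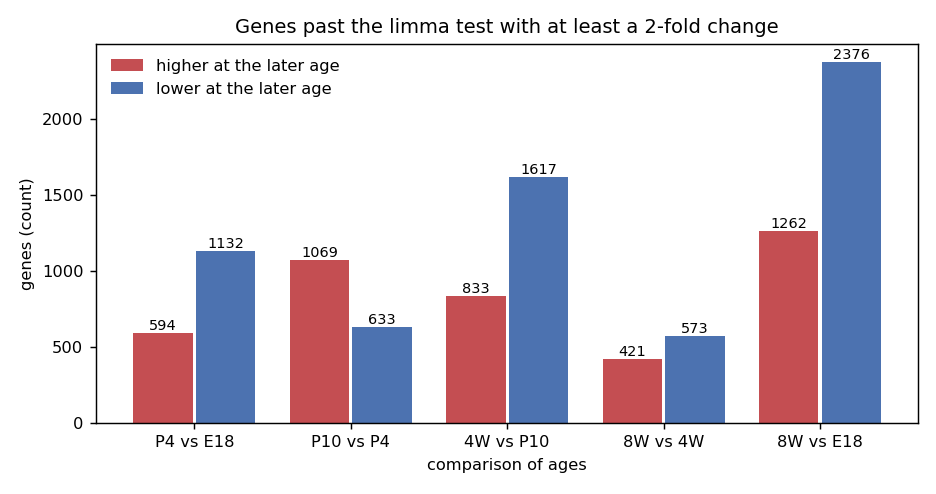
Number of genes (y axis) past the limma test with at least a 2-fold change, for each comparison of ages (x axis), higher or lower at the later age. From P10 to 4W 833 genes rose and 1617 fell by at least 2-fold, and from E18 to 8W 1262 rose and 2376 fell, but scaling by the array median reverses both balances (1659 up and 964 down, 2235 up and 1544 down).

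Over birth and the first postnatal days, Dio2 and Ppargc1a rose and most genes of fat synthesis fell. From E18 to P4, Dio2, the deiodinase that makes active thyroid hormone inside brown adipocytes, rose 9.31-fold (log2 3.22 ± 0.05), and Ppargc1a, a coactivator of mitochondrial and thermogenic genes, rose 9.08-fold (log2 3.18 ± 0.05). Ucp1, the uncoupling protein that lets mitochondria release heat, rose 1.61-fold from an already high level (log2 0.69 ± 0.15). Fasn, the fatty acid synthase, fell 10.7-fold (log2 -3.42 ± 0.07). Nnat, an imprinted gene for a small membrane proteolipid, rose most, by 167-fold (log2 7.39 ± 0.06). All of these had limma adjusted p of 0.0017 or below and non-overlapping arrays at the 2 ages.

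The thermogenic brown fat list did not move as a group from E18 to P4: 10 of 21 members rose, 8 fell and 3 did not pass (median log2 0.079, limma camera adjusted p = 0.52), and adjusted over the list alone the counts were 10 and 8. The remaining genes of the fixed panel changed by less than 2-fold. Prdm16, a regulator of brown fat identity, rose 1.24-fold, and Mki67, a marker of dividing cells, rose 1.35-fold. Elovl3, a fatty acid elongase of brown fat, fell 1.79-fold, and Dlk1, an imprinted preadipocyte factor, fell 1.46-fold. Cox7a1, a subunit of cytochrome oxidase, fell 1.15-fold (limma adjusted p = 0.042), a call that ended with slide as a block. Cidea, Adipoq, Lep and Igf2 did not pass the test, with log2 changes of -0.12 ± 0.09, -0.08 ± 0.07, -0.02 ± 0.10 and -0.35 ± 0.22. The Igf2 levels of the 2 ages did not overlap, and Igf2 passed within slide 1 (log2 -0.37, limma adjusted p = 0.00024, between 0.00024 and 0.32 over the alternatives), with the arrays of these ages alone and with array weights. Cidea and Adipoq also passed as falls with array weights, and Cidea without P4 replicate 3. Among the other genes with the largest rises, Adcy3, an adenylyl cyclase, rose 19.1-fold and Atf3, a stress-induced transcription factor, 19.5-fold. Retnla, a resistin-like secreted protein, was at least 12.9-fold higher at P4, and Mfsd2a, a lipid transporter, at least 10.7-fold. Neither was well above background on any E18 array, so these are lower bounds: the mean of the bright age against the mean at the dim age of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The largest falls were in the major urinary protein genes: Mup18 was at least 188-fold lower at P4, Mup1 at least 122-fold and Mup17 at least 116-fold, and Mup19, measured above background on 1 of 4 P4 arrays, fell 211-fold. These genes are near-identical copies, so their probes may share signal. They are abundant in liver, and of the 8 measured genes of the liver marker list 4 fell, each by at least 2-fold, and none rose (median log2 -0.89, with 1 gene at its bound or not, limma camera adjusted p = 0.031, between 0.0038 and 0.21 over the alternatives). That list's call ended with an estimated correlation, when slide entered the fit and within slide 1 (medians of -0.54 and -0.58), and with normexp background correction, array weights and P4 replicate 1 left out.

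By gene list, 22 of the 44 fixed lists moved from E18 to P4 by the camera test of limma, 7 of them also with an estimated correlation between genes. In the fatty acid and triglyceride synthesis list 16 of 22 members fell and 5 rose (median log2 -1.28, limma camera adjusted p = 5.1e-05). Scd1 and Scd2, desaturases of newly made fatty acids, fell 8.71-fold and 7.52-fold. In the antigen presentation list 14 of 18 members rose and none fell (median log2 0.48, limma camera adjusted p = 8e-07). H2-Ab1 and Cd74, a class II molecule and its chaperone, rose 8.01-fold and 6.36-fold, while H2-Aa, above background on 1 of 3 E18 arrays, rose 5.27-fold. Lymphocyte markers rose in the same comparison, 9 of 18 up and 1 down (median log2 0.34, with 2 genes at their bound or not, limma camera adjusted p = 0.019, between 0.0045 and 0.29 over the alternatives), a call that ended with an estimated correlation and with only probes above background on all arrays. In the respiratory chain list 35 of 46 subunits fell and 11 did not pass (median log2 -0.30, limma camera adjusted p = 2e-06, limma adjusted p = 0.21 with an estimated correlation). Its largest falls were in Atp5c1 (1.83-fold), Ndufa1 (1.64-fold) and Ndufb5 (1.49-fold). In the interferon response list 17 of 21 members fell and 1 rose (median log2 -0.91, limma camera adjusted p = 1.8e-05, limma adjusted p = 0.069 with an estimated correlation). Ifi44 and Rtp4 fell 4.1-fold and 2.95-fold, and the chemokine gene Cxcl10 rose 2.6-fold. In the list of neutrophils and their precursors 10 of 12 genes fell (median log2 -2.31, and -2.20 with 3 genes at their bound). Camp and Ltf, of neutrophil granules, fell 9.79-fold and 8.78-fold, and S100a9 fell 7.78-fold.

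Markers of skeletal muscle moved with the same comparison. All 22 measured genes of the skeletal muscle list fell from E18 to P4 (median log2 -3.60, and -2.99 with 4 genes at their bound, limma camera adjusted p = 1.2e-14). Ckm, the muscle creatine kinase, fell 30.3-fold, Ttn, the giant sarcomere protein, fell 26.9-fold, and Myot, above background on 1 of 4 P4 arrays, fell 29.3-fold. In the list of developing skeletal muscle 10 of 12 genes fell (median log2 -2.68, and -2.0003 with 3 genes at their bound). Actc1 and Myh3, embryonic forms of actin and myosin, fell 112-fold and 83.3-fold, and Tnnt2, above background on 1 of 4 P4 arrays, fell 21.8-fold. The falls in Mup, respiratory chain and neutrophil genes above were measured in these same samples.

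Over all genes, 4305 rose and 4772 fell from E18 to P4, 594 and 1132 of them by at least 2-fold. In 10243 genes the arrays of the 2 ages did not overlap, a rank pattern that chance gives for 5.71% of genes. When slide entered the fit, 9302 genes passed, and within slide 1, which holds 3 arrays of each age, 9802. Dio2 rose by 3.20 and Ppargc1a by 3.19 (log2) within slide 1. With slide as a block the list medians were -1.30 for fat synthesis, 0.46 for antigen presentation, -0.30 for the respiratory chain, -0.88 for the interferon response, -2.33 for neutrophils, -3.52 for skeletal muscle and -2.60 for developing muscle. Within slide 1 they were -1.29, 0.46, -0.29, -0.83, -2.25, -3.54 and -2.53. Adjusted over the list alone, 16 fat synthesis genes fell, 14 antigen presentation genes rose, 38 respiratory chain genes fell, 18 interferon genes fell and all 22 muscle genes fell.

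**Figure D2:**
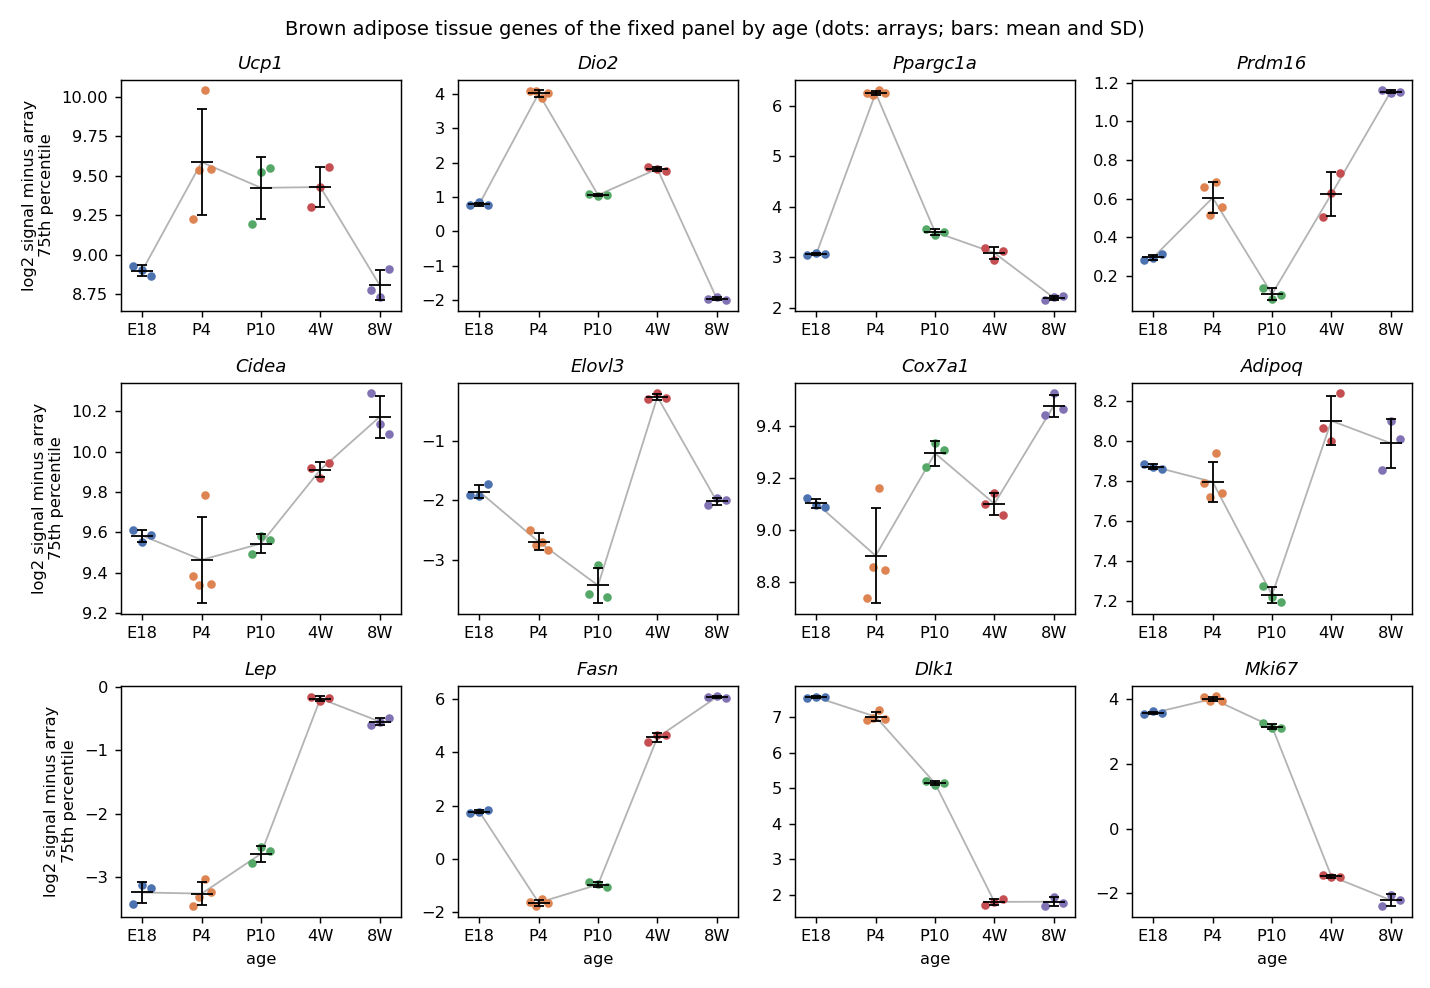
Level of 12 genes of the fixed panel (y axis, log2 signal minus the 75th percentile of the array) at each age (x axis), with dots for arrays and bars for the mean and SD. Dio2 and Ppargc1a peak at P4, and Dlk1 and Mki67 fall from P10 to 4W while Fasn rises.

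Within the suckling period Dio2 and Ppargc1a came down from their P4 peak. From P4 to P10 Dio2 fell 7.74-fold (log2 -2.95 ± 0.05) and Ppargc1a fell 6.72-fold (log2 -2.75 ± 0.05), while Ucp1 did not pass the test (log2 -0.16 ± 0.15, limma adjusted p = 0.41). The growth genes Igf2 and Dlk1 fell 3.38-fold and 3.67-fold, and Mki67 fell 1.81-fold. Prdm16 fell 1.41-fold and Elovl3 1.66-fold. Cox7a1 rose 1.31-fold, Fasn 1.6-fold and Lep, the satiety hormone gene, 1.54-fold, though the Lep call ended with normexp background correction. Adipoq, the adiponectin gene, fell 1.48-fold, a call that ended within slide 2, where 1 array of each age is compared and the spread comes from the 4W and 8W arrays alone. Cidea did not pass (log2 0.08 ± 0.09), except as a rise with array weights or without P4 replicate 3. In the thermogenic brown fat list 6 of 21 members rose, 8 fell and 7 did not pass (median log2 -0.16, limma camera adjusted p = 0.57), with 6 and 8 adjusted over the list alone. Of the other genes with the largest falls, Mfsd2a was at least 10.5-fold lower at P10. Bex4, an X-linked gene, fell 15-fold and Pde6a, a phosphodiesterase, fell 14-fold, each above background on 2 of 3 P10 arrays.

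Dividing-cell and growth genes fell from P4 to P10 while interferon response, antigen presentation and endothelial genes rose. In the cell division list 32 of 34 members fell and 1 rose (median log2 -0.98, limma camera adjusted p = 1.2e-10). Rrm2, a ribonucleotide reductase subunit, fell 3.84-fold, the cyclin gene Ccnb1 2.95-fold and the replication gene Mcm5 2.57-fold. In the imprinted growth gene list 14 of 17 members fell and 2 rose (median log2 -1.26, limma camera adjusted p = 2.5e-05). Peg3 fell 5.68-fold, Plagl1 4.72-fold and Zdbf2, above background on 2 of 3 P10 arrays, 5.57-fold. In the collagen and extracellular matrix list 19 of 27 members fell and 2 rose (median log2 -0.65, limma adjusted p = 0.060 with an estimated correlation). Fbn2, Mfap5 and Lox, which build and crosslink elastic fibres, fell 3.59-fold, 2.56-fold and 2.3-fold. All 21 interferon response genes rose (median log2 1.35, limma camera adjusted p = 2.4e-11), with Ifit3 up 3.72-fold, Gbp3 3.68-fold and Ifit1 3.58-fold. In the antigen presentation list 17 of 18 members rose (median log2 1.14, limma camera adjusted p = 1.1e-10), with H2-Aa up 4.19-fold, Cd74 3.84-fold and H2-DMb1 3.35-fold. In the endothelial list 15 of 18 members rose and none fell (median log2 0.59, limma adjusted p = 0.061 with an estimated correlation). Tie1, Emcn and Esam, of the endothelial surface, rose 2.91-fold, 2.24-fold and 1.96-fold.

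Skeletal muscle markers and sex-linked transcripts also differed between P4 and P10. All 22 muscle genes rose (median log2 3.74, and 3.41 with 4 genes at their bound, limma camera adjusted p = 2.2e-17). The fast myosin genes Myh1 and Myh2 rose 126-fold and 39.8-fold, and Myh4, above background on 1 of 4 P4 arrays, rose 194-fold. Ckmt2, the mitochondrial creatine kinase of striated muscle, was at least 40.3-fold higher at P10. Xist, the RNA that silences an X chromosome in female cells, was at least 42.4-fold higher at P10, and was well above background on all 3 P10 arrays and on no P4 array. The Y-linked Ddx3y was at least 162-fold lower at P10, and Eif2s3y, above background on 1 of 3 P10 arrays, fell 194-fold. Lymphocyte markers rose too: 14 of 18 genes of that list rose and none fell (median log2 1.73, and 1.07 with 3 genes at their bound, limma camera adjusted p = 4e-05), with 14 up adjusted over the list alone. Its median was 1.73 with slide as a block, 1.51 within slide 1 and 1.65 within slide 2. The macrophage list did not pass, with a mean level of -0.0019 at P4 and -0.21 at P10, relative to its mean over the ages. The interferon, antigen presentation, endothelial and matrix changes above were measured in these same P10 arrays.

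From P4 to P10, 4342 genes rose and 4580 fell, 1069 and 633 by at least 2-fold, and the arrays did not overlap in 8802 genes, against the same chance share of 5.71%. In a fit with a slide term 9373 genes passed. Within slide 1, with 3 P4 and 2 P10 arrays, 9289 passed, and within slide 2 5350 passed (3030 up and 2320 down), a comparison of 1 array with 1 that assumes they vary like the 4W and 8W arrays. When slide entered the fit the list medians were -0.99 for cell division, -1.25 for imprinted genes, -0.66 for matrix, 1.35 for interferon response, 1.13 for antigen presentation, 0.59 for endothelial cells and 3.75 for muscle. Within slide 1 they were -1.01, -1.31, -0.67, 1.33, 1.12, 0.57 and 3.68, and within slide 2 -0.95, -1.11, -0.76, 1.43, 1.15, 0.65 and 3.93. The calls of Ifit1 and Mfsd2a also ended within slide 2. Adjusted over the list alone, 32 cell division and 15 imprinted genes fell, and 21 interferon, 17 antigen presentation, 15 endothelial and 22 muscle genes rose.

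**Figure D3:**
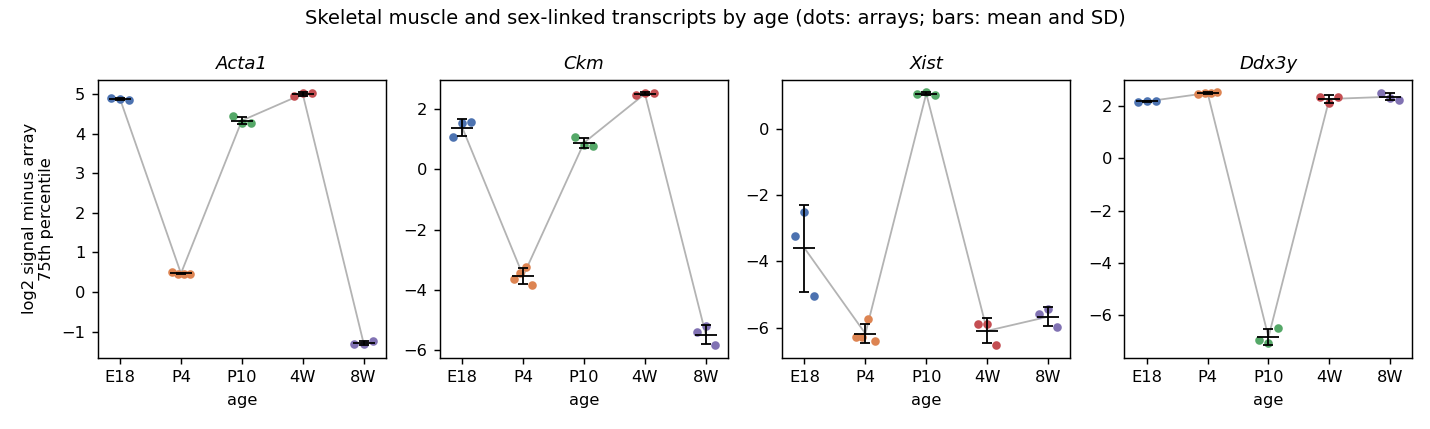
Level of the muscle genes Acta1 and Ckm and of the sex-linked Xist and Ddx3y (y axis, log2 signal minus the 75th percentile of the array) at each age (x axis), with dots for arrays and bars for the mean and SD. Xist lies near 1.06 on the P10 arrays, where Ddx3y lies near -6.84.

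Between the suckling period and 4 weeks, cell division genes fell and lipid synthesis genes rose. From P10 to 4W Mki67 fell 24.9-fold (log2 -4.64 ± 0.08) and Fasn rose 46.0-fold (log2 5.52 ± 0.08). Lep rose 5.44-fold (log2 2.44 ± 0.10) and Elovl3 8.95-fold (log2 3.16 ± 0.12). Dlk1 fell 10.1-fold (log2 -3.34 ± 0.08), and Igf2, above background on 2 of 3 arrays at 4W, fell 14.2-fold (log2 -3.83 ± 0.23). Ucp1 did not pass the test (log2 0.0050 ± 0.16, limma adjusted p = 0.98). Adipoq rose 1.83-fold, Dio2 1.69-fold, Prdm16 1.43-fold and Cidea 1.29-fold. Ppargc1a fell 1.33-fold, a call that ended with scaling by the array median, and Cox7a1 did not pass (log2 -0.19 ± 0.08, limma adjusted p = 0.061), although it passed as a fall under 10 of the alternative settings. The thermogenic brown fat list rose over this interval, with 13 of 21 members up and 2 down (median log2 0.52, limma camera adjusted p = 0.0013, and 0.041 with an estimated correlation), and with 14 and 3 adjusted over the list alone. Its median was 0.54 with slide as a block and 0.49 within slide 2.

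Of the 44 lists, 31 moved from P10 to 4W by camera, 19 of them also with an estimated correlation. In the cell division list 32 of 34 members fell and none rose (median log2 -2.92, and -2.54 with 4 genes at their bound, limma camera adjusted p = 1.6e-20). The spindle gene Prc1 fell 25.8-fold, and the kinase gene Melk was at least 10.2-fold lower at 4W. In the fatty acid and triglyceride synthesis list 21 of 22 members rose (median log2 1.39, limma camera adjusted p = 2e-13). Scd1 rose 20.3-fold, and Acaca, the carboxylase that commits carbon to fatty acids, 10.6-fold. In the general adipocyte list 17 of 22 members rose and none fell (median log2 0.69, limma adjusted p = 0.052 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter, rose 3.48-fold, the lipid droplet gene Plin4 2.65-fold and the lipase gene Lipe 2.17-fold. In the glycolysis and glucose uptake list 16 of 17 members rose (median log2 0.60, limma camera adjusted p = 7e-07). Its size depends on the scaling, with a median of 0.36 with quantile normalization and 0.91 with scaling by the array median. Hk2, a hexokinase, rose 3.8-fold, Pfkl, a phosphofructokinase subunit, 2.86-fold, and Pfkfb3, which makes an activator of that enzyme, 2.42-fold.

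Matrix, endothelial and interferon genes fell over the same interval. In the collagen and extracellular matrix list 22 of 27 members fell and none rose (median log2 -0.97, limma camera adjusted p = 3.1e-09). The collagen genes Col5a2 and Col15a1 fell 4.14-fold and 4.1-fold, and Fbn2, above background on 1 of 3 arrays at 4W, fell 3.66-fold. In the endothelial list 17 of 18 members fell and 1 rose (median log2 -0.79, limma camera adjusted p = 8.1e-08). Cldn5, of endothelial tight junctions, fell 6.98-fold, the transcription factor gene Erg 2.87-fold and Robo4 2.11-fold. In the interferon response list 15 of 21 members fell and 1 rose (median log2 -0.65, limma camera adjusted p = 1.7e-06), with Cxcl10 down 4.53-fold, Ifi44 3.47-fold and Ifit2 3.39-fold. Lymphocyte, neutrophil and mast cell markers fell with them, each list also past the test with an estimated correlation. Of 18 lymphocyte genes 12 fell and none rose (median log2 -0.80, with 4 genes at their bound or not, limma adjusted p = 0.031 with an estimated correlation). Of 12 genes of neutrophils and their precursors 8 fell and 1 rose (median log2 -1.33, and -1.07 with 4 genes at their bound, limma adjusted p = 0.019 with an estimated correlation), and of 8 mast cell genes 7 fell and none rose (median log2 -0.91, limma adjusted p = 0.041 with an estimated correlation). The medians of these lists were -0.86, -1.25 and -0.96 with slide as a block and -1.01, -1.44 and -0.95 within slide 2. The macrophage list rose instead (median log2 0.39, limma camera adjusted p = 0.0075). Its median was 0.28 with slide as a block and 0.19 within slide 2. Antigen presentation genes rose as well (median log2 0.57, limma camera adjusted p = 0.00045). Beside these, 18 of 22 skeletal muscle genes rose and 1 fell (median log2 1.14, limma camera adjusted p = 9.9e-06). The largest rises were in Cyp2b10, a drug-metabolising cytochrome gene (768-fold, above background on 2 of 3 P10 arrays), and in Ddx3y, Eif2s3y, Mup18 and Mup1. Eif2s3y, above background on 1 of 3 P10 arrays, rose 311-fold. Ddx3y was at least 138-fold, Mup18 at least 82.4-fold and Mup1 at least 59.4-fold higher at 4W. In the liver marker list 4 of 8 genes rose and none fell, without passing (median log2 0.85, limma camera adjusted p = 0.079). The largest falls were in Xist, at least 35.5-fold, in Cstdc5 and Stfa1, cystatin-family genes of myeloid cells (at least 30.9-fold and 23.2-fold), in the protease gene Adamts17 (at least 16.1-fold) and in the imprinted gene Mest (39.3-fold).

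Clock and glucocorticoid genes and immune cell markers were examined after their values were seen. From P10 to 4W the clock output gene Dbp rose 12-fold and Nr1d1, a repressor of the clock, 5.67-fold, while Arntl, which drives both, fell 9.82-fold and was above background on 2 of 3 arrays at 4W. The glucocorticoid targets Zbtb16 and Fkbp5 rose 7.55-fold and 4.24-fold, as 2 members picked from a list with a median log2 change of 0.91. Ms4a1, a lymphocyte gene, was at least 19.6-fold lower at 4W, and S100a8, of neutrophils, fell 12.2-fold. From P10 to 4W 5022 genes rose and 4408 fell (53.3% up), 833 and 1617 by at least 2-fold, and the arrays did not overlap in 10026 genes, where chance gives 10% for 3 arrays against 3. Scaling by the array median changes the median log2 change of all genes from -0.017 to 0.29 and gives 6734 genes up and 2091 down (76.3% up). The excess of falls among the genes changed by at least 2-fold then reverses, to 1659 up and 964 down, and it is also absent with normexp background correction (641 up and 592 down) and with only probes above background on all arrays (627 up and 593 down).

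With slide as a block 8541 genes passed between P10 and 4W, and within slide 2, with 1 P10 array against 3, 6779 passed, the P10 array being assumed to vary like those of 4W and 8W. With slide as a block the list medians were -2.94 for cell division, 1.36 for fat synthesis, 0.71 for adipocyte genes, 0.62 for glycolysis, -0.97 for matrix, -0.84 for endothelial cells, -0.85 for interferon response and 1.11 for muscle. Within slide 2 they were -2.90, 1.32, 0.64, 0.56, -0.97, -0.93, -0.85 and 1.00. Adjusted over the list alone, 32 cell division, 22 matrix, 17 endothelial and 15 interferon genes fell, and 21 fat synthesis, 17 adipocyte, 16 glycolysis and 18 muscle genes rose. The respiratory chain list had a median of 0.16 with 17 of 46 members up (limma adjusted p = 0.43 with an estimated correlation), and turned to -0.11 with quantile normalization.

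**Figure D4:**
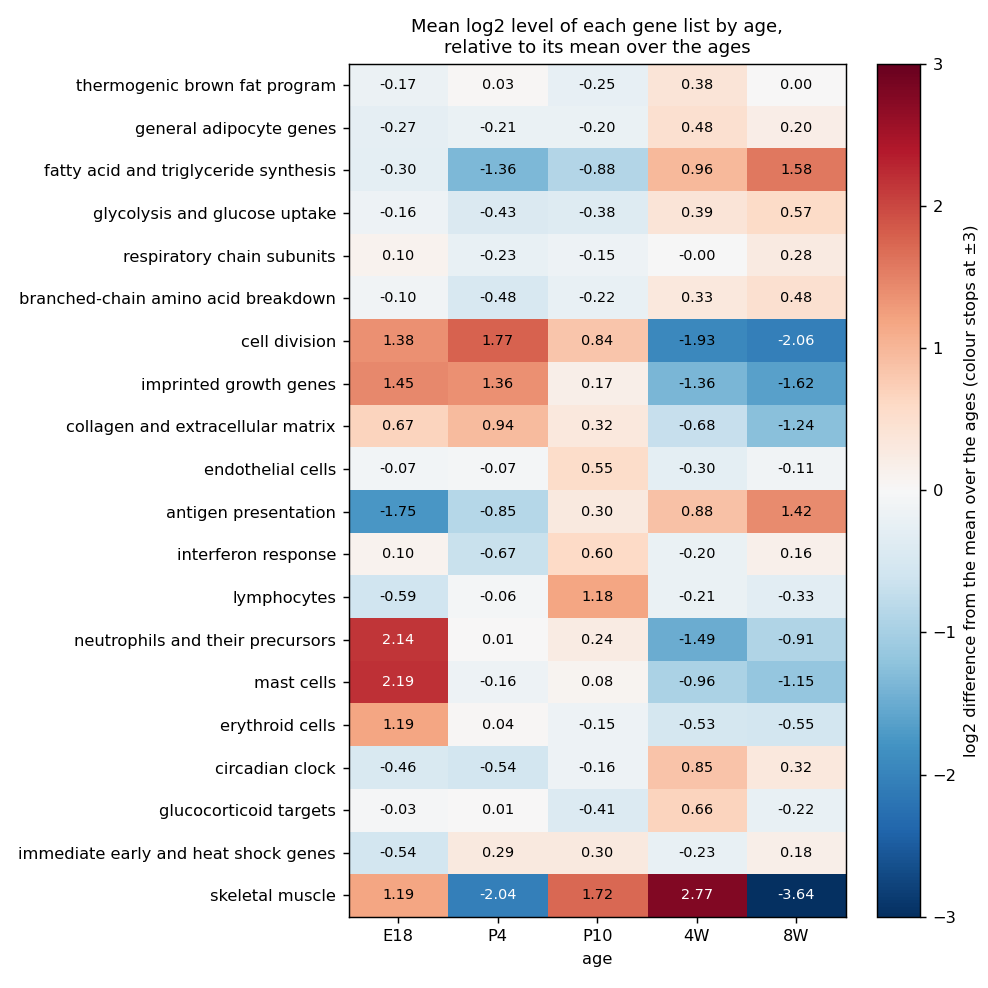
Mean log2 level of 20 gene lists (y axis) at each age (x axis), relative to the mean over the ages, with colour for the same value. Cell division lies at 1.77 at P4 and -2.06 at 8W, and skeletal muscle at 2.77 at 4W and -3.64 at 8W.

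From 4 to 8 weeks the thyroid hormone deiodinase fell and lipid synthesis rose further. Dio2 fell 13.7-fold (log2 -3.77 ± 0.06), Elovl3 3.37-fold (log2 -1.75 ± 0.12), Ppargc1a 1.85-fold (log2 -0.89 ± 0.06) and Ucp1 1.54-fold (log2 -0.62 ± 0.16). Fasn rose 2.87-fold (log2 1.52 ± 0.08) and Prdm16 1.44-fold (log2 0.53 ± 0.06). Mki67 fell 1.67-fold and Lep 1.29-fold, the latter not passing with normexp background correction. Cox7a1 rose 1.3-fold, a call that ended with quantile normalization and with scaling by the median. Cidea rose 1.2-fold at a limma adjusted p of 0.0496, and 23 of the alternative settings ended that call. Adipoq, Dlk1 and Igf2 did not pass, with log2 changes of -0.11 ± 0.08, 0.0033 ± 0.08 and -0.38 ± 0.23. Adipoq passed as a fall with quantile normalization and with the submitters' series matrix. Dlk1 fell by 0.19 when all kept probes of the gene were averaged.

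Skeletal muscle transcripts fell far in the 8W samples. All 22 genes of the list fell from 4W to 8W (median log2 -6.62, and -5.48 with 14 genes at their bound, limma camera adjusted p = 3.5e-31). Myh8, Myh4, Tnnt3 and Myh2, of the sarcomere, were at least 894-fold, 586-fold, 304-fold and 133-fold lower at 8W, and Tnni2 fell 370-fold. Beside this, 36 of 46 respiratory chain subunits rose and none fell (median log2 0.29, limma camera adjusted p = 1e-07, limma adjusted p = 0.15 with an estimated correlation). The median of this list was 0.13 with quantile normalization and 0.24 with scaling by the median. Ndufs3, Ndufs8 and Uqcrq rose 1.43-fold, 1.39-fold and 1.36-fold, although the call of Ndufs8 ended with scaling by the median and that of Uqcrq with the submitters' series matrix. In the collagen and extracellular matrix list 20 of 27 members fell and 1 rose (median log2 -0.70, limma camera adjusted p = 5.1e-09). Mfap5 fell 2.93-fold, Eln, the elastin gene, above background on 2 of 3 arrays at 8W, 2.38-fold, and Thbs2 was at least 2.27-fold lower. Markers of adipose progenitors and mesenchyme, cells that make matrix, fell as well: 11 of 17 fell and 2 rose (median log2 -0.24, with 1 gene at its bound or not, limma camera adjusted p = 0.0045, between 0.0028 and 0.14 over the alternatives, the highest with an estimated correlation), with 11 down adjusted over the list alone.

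Fat synthesis and antigen presentation genes rose between 4W and 8W. In the fat synthesis list 15 of 22 members rose and 4 fell (median log2 0.67, limma camera adjusted p = 3.7e-05). Acss2, which makes acetyl-CoA from acetate, rose 4.99-fold, Scd2 4.45-fold and Slc25a1, the mitochondrial citrate carrier, 2.96-fold. In the antigen presentation list 11 of 18 members rose and none fell (median log2 0.56, limma camera adjusted p = 3.6e-06), with Psmb9 up 2.32-fold and Tap1 and Nlrc5 each 2.24-fold. In the glucocorticoid target list 8 of 10 members fell and 1 rose (median log2 -0.65, limma adjusted p = 0.14 with an estimated correlation), with Zbtb16 down 7.15-fold, Fkbp5 5.41-fold and Mt2, a metallothionein gene, 2.41-fold. In the interferon list 12 of 21 members rose and 1 fell (median log2 0.25, limma adjusted p = 0.14 with an estimated correlation). Cxcl10 rose 5.13-fold and Gbp3 1.82-fold, and Irf7 fell 1.71-fold, a call that ended within slide 2. Arntl rose 8.63-fold and Dbp fell 3.16-fold. Sgip1, which acts in energy balance, was at least 86.7-fold higher at 8W, the matrix gene Fras1 at least 7.12-fold and the odorant receptor gene Olfr1305 at least 7.09-fold. Syt10, a synaptotagmin gene, rose 20.4-fold and Prr32, above background on 1 of 3 arrays at 4W, 9.51-fold.

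From 4W to 8W 3345 genes rose and 3373 fell (49.8% up), 421 and 573 by at least 2-fold, and the arrays did not overlap in 8921 genes, where chance gives 10%. Scaling by the array median gives 1185 genes up and 2070 down (36.4% up). All arrays of both ages lie on slide 2, so a slide block leaves each change as it is, with the muscle median at -6.62, matrix at -0.70, the respiratory chain at 0.29, antigen presentation at 0.56, fat synthesis at 0.67, glucocorticoid targets at -0.65 and interferon response at 0.25. With the block 7329 genes passed, and with the slide 2 arrays alone 6314. Adjusted over the list alone, 22 muscle, 20 matrix and 8 glucocorticoid genes fell, and 40 respiratory chain, 13 antigen presentation, 15 fat synthesis and 12 interferon genes rose.

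From the first to the last age, brown fat lost growth transcripts and gained lipid synthesis and antigen presentation transcripts. Between E18 and 8W Dlk1 fell 54.0-fold (log2 -5.76 ± 0.08) and Mki67 55.7-fold (log2 -5.80 ± 0.08), and Igf2 was at least 75.7-fold lower. Fasn rose 19.7-fold (log2 4.30 ± 0.08) and Lep 6.45-fold (log2 2.69 ± 0.10). Dio2 fell 6.71-fold and Ppargc1a 1.82-fold, while Prdm16 rose 1.81-fold and Cidea 1.51-fold. Ucp1, Elovl3 and Adipoq did not pass, with log2 changes of -0.09 ± 0.16, -0.16 ± 0.12 and 0.12 ± 0.08. Ucp1 passed as a fall with quantile normalization and with the series matrix, and Adipoq as a rise with quantile and median scaling. Cox7a1 rose 1.3-fold, and its log2 change turned to -0.15 with the submitters' series matrix.

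All 34 cell division genes fell from E18 to 8W (median log2 -3.56, and -3.02 with 5 genes at their bound, limma camera adjusted p = 7e-18), with Tpx2 and Top2a at least 20.8-fold and 18.2-fold lower. Markers of blood cells and their precursors fell too. In the list of neutrophils and their precursors 11 of 12 genes fell and none rose (median log2 -3.18, and -2.50 with 5 genes at their bound, limma adjusted p = 0.0054 with an estimated correlation), and in the erythroid list 14 of 18 fell and 1 rose (median log2 -1.77, and -1.48 with 6 genes at their bound, limma adjusted p = 0.0076 with an estimated correlation). With a slide term their medians were -3.31 and -1.92. In the imprinted growth list 16 of 17 genes fell and 1 rose (median log2 -2.96, and -2.71 with 3 genes at their bound), with Mest down 242-fold and Plagl1 74.5-fold. In the matrix list 24 of 27 genes fell and 1 rose (median log2 -2.16), with Fbn2 and Thbs2 at least 33.0-fold and 11.4-fold lower and Col14a1 down 7.87-fold. All 18 antigen presentation genes rose (median log2 2.88, limma camera adjusted p = 9.9e-14), with H2-Ab1 up 84.0-fold and Cd74 61.9-fold. H2-Aa, above background on 1 of 3 E18 arrays, rose 76.4-fold. In the fat synthesis list 19 of 22 genes rose and 2 fell (median log2 1.89), with Pnpla3, a lipid droplet protein gene, up 17.0-fold and the elongase gene Elovl6 16.5-fold. In the list of branched-chain amino acid breakdown 16 of 18 genes rose and 1 fell (median log2 0.53, limma camera adjusted p = 8.6e-05), with Auh, Ivd and Bckdha up 3.03-fold, 2.78-fold and 2.63-fold. All 22 skeletal muscle genes fell over the same interval (median log2 -4.28, and -3.74 with 14 genes at their bound). Sln, a regulator of the muscle calcium pump, was at least 375-fold lower at 8W, and Myh8 and Actc1 at least 469-fold and 340-fold. Tnnt3 was at least 167-fold lower, Myh3 at least 115-fold and Ttn at least 44.2-fold, and Tnni2 fell 257-fold. The largest rises were in Retnla and Sgip1, at least 204-fold and 148-fold, in Vat1l, at least 123-fold, in H2-Q10, a non-classical class I gene, 150-fold, and in the chemokine gene Cxcl14, above background on 2 of 3 E18 arrays, 155-fold.

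Between E18 and 8W 5101 genes rose and 5651 fell (47.4% up), 1262 and 2376 by at least 2-fold, and the arrays did not overlap in 12880 genes, where chance gives 10%. Scaling by the array median changes the median log2 change of all genes from -0.079 to 0.25 and gives 6682 genes up and 2961 down (69.3% up). By at least 2-fold it gives 2235 up and 1544 down, so the excess of falls reverses, as it does with only probes above background on all arrays (1010 up and 795 down) and without a filter on dim probes (2634 up and 2364 down). With normexp background correction the 2-fold counts were 1001 up and 996 down. No slide holds both ages, so no within-slide value can be had. In a fit with a slide term, which rests on the P4 and P10 arrays, 8997 genes passed, and the list medians were -3.63 for cell division, -3.15 for imprinted genes, -2.22 for matrix, 2.84 for antigen presentation, 1.80 for fat synthesis, 0.54 for branched-chain amino acid breakdown and -4.29 for muscle. Adjusted over the list alone, 34 cell division, 16 imprinted, 24 matrix and 22 muscle genes fell, and 18 antigen presentation, 19 fat synthesis and 16 branched-chain amino acid genes rose.

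The changes over birth and those after the suckling period ran in opposite directions at more genes than independent lists would share. Of the 4305 genes that rose from E18 to P4, 1552 fell from P10 to 4W, against 1154.57 for independent lists (two-sided Fisher's exact test over genes, p = 6.7e-55). Of the 4772 genes that fell to P4, 2104 rose to 4W, against 1458.08 (two-sided Fisher's exact test, p = 5.2e-124). Scaling by the array median left 608 genes that rose and then fell, from 3358 that rose to P4 and 2091 that fell to 4W. The value of 1154.57 does not apply to these shorter lists. Fasn and Scd1 fell to P4 and rose to 4W, and Atf3 rose 19.5-fold to P4 and fell 2.71-fold to 4W. Genes that rose in both intervals also exceeded independence, by less (1411 against 1315.39, two-sided Fisher's exact test, p = 0.00025). Without a fold limit, genes that fell in both were fewer than independent lists would share (1096 against 1279.81, two-sided Fisher's exact test, p = 6.9e-13). By at least 2-fold in both intervals, 115 genes rose and then fell and 211 fell and then rose. At that limit 60 rose in both and 166 fell in both. No value for independent lists was computed at that limit, so a departure from independence there was not tested. The paired comparisons share no arrays, and genes are not independent replicates. When slide entered the fit the counts were 1520 and 1953.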

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

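The comparisons of single arrays here followed a rule fixed beforehand, and no test in this part was chosen after a result was seen. Only P4 has enough arrays for it: 76 genes, 28 gene lists and 4 measures per array were examined for 1 of its 4 arrays lying far from the others, and chance alone picks out about 1 in 20 groups. It picked out 5 genes, 4 lists and 1 array measure, 6 of them at P4 replicate 3 and 4 at P4 replicate 1. In P4 replicate 3, which has the lowest 75th percentile of signal (351), Cidea lay at 9.78 (log2, relative to the 75th percentile) against 9.34 to 9.39 in the others. Dlk1 lay at 7.21 there against 6.93 to 6.97, and the embryonic globin gene Hba-x at -5.53 against -6.19 to -6.08, on arrays where it was not well above background. The mean of the fatty acid oxidation list was -0.040 in that array against -0.17 to -0.15, that of the citric acid cycle list -0.21 against -0.35 to -0.34, and that of the immediate early list 0.38 against 0.25 to 0.27. In P4 replicate 1, the P4 array on slide 2, Ifit3 lay at -1.02 against -1.69 to -1.60, Camp at -1.54 against -1.47 to -1.46 and the mean of the liver list at -1.28 against -0.69 to -0.60. That array also had 200 marked spots against 162 to 167. No explanation was tested for these values.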

How the results depend on the processing

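Of 112 gene list results past camera, with a list counted once in each comparison, 47 kept their direction and call under every alternative run. Under every one but the estimated correlation 86 did. The estimated correlation left 7 lists for P4 versus E18, 6 for P10 versus P4, 19 for 4W versus P10, 6 for 8W versus 4W and 11 for 8W versus E18. Of 225 named gene results past the test, 211 kept their direction and call under every alternative that measured them, and of 14 not past it 5 stayed so. Many of the named genes are not measured when only probes above background on all arrays are used. Genes outside the fixed panel were named for their large changes, so most were likely to keep their call. Median scaling gave 1205 genes highest at E18, 2139 at 4W, 3255 genes for 8W versus 4W, 608 that rose to P4 and fell to 4W, and turned the DNA methylation list of 4W versus P10 to 0.033. The balance of rises and falls by at least 2-fold reversed under some settings for 4W versus P10 and 8W versus E18, and kept its direction for the other comparisons; without a fold limit it changed direction under some setting in every comparison. Normexp gave 768 genes highest at E18, 962 at P4 and 480 at P10. Without a filter on dim probes 2617 genes were highest at 8W, while the other ages kept counts within 1.5 times. With probes above background on all arrays 653 were highest at E18, 923 at P4 and 544 at P10, fewer genes being tested, and the calcium, creatine and lipid cycling list of 8W versus 4W turned to 0.040. For 4W versus P10 the respiratory chain list turned to -0.11 and the citric acid cycle list to -0.082 with quantile normalization, and both to -0.11 with the series matrix (-0.113 and -0.114). The series matrix also turned Cox7a1 to -0.15 for 8W versus E18, and the mean of probes turned Dlk1 to -0.19 for 8W versus 4W. Slide 2 alone, with 1 array per age, gave 5350 genes for P10 versus P4. Apart from the settings with fewer genes or arrays the cause was not tested, the rise at 8W without a filter included. Leaving out 1 array moved no count by more than 1.5 times, but the Cidea call for 8W versus 4W ended without any one array except P4 replicate 2 or 3. Signal over background limits the folds given as bounds. Over all ages the replicate numbers gave no clear sign of pairing: over 30 pairs with the same number the median correlation was -0.0046, and 7 of 16 arrays correlated best with their own number. The highest, 0.50, was between P4 replicate 1 and P10 replicate 1, both on slide 2. Arrays of E18, 4W and 8W with the same number correlated at 0.030 to 0.093, and those with different numbers at -0.072 to 0.0039. A weak pairing at these ages is therefore not excluded. With a replicate block 13674 genes passed the F test, and 8599, 8420, 9208, 6391 and 10559 the comparisons in the order of the report. The settings chosen after seeing the data gave F test counts of 13896 without the P10 arrays, 13737 without genes that follow muscle markers and 14458 without the arrays on the other slide.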

Other observations

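The tests on unequal muscle carry-over, scaling, 1 mislabelled array and the slides, and the comparisons of 4W with E18 and 8W with P4, were chosen only after the results were seen. Genes of blood-borne and tissue immune cells changed between the ages beside the programs described above, and those named here were chosen after their values were seen. From E18 to P4 7 of 8 mast cell genes fell and 1 rose (median log2 -2.68, limma adjusted p = 0.056 with an estimated correlation), with Cpa3 and Cma1, proteases of mast cell granules, down 16.9-fold and 8.37-fold. Between E18 and 8W Cpa3 fell 186-fold. In the erythroid list 11 of 18 genes fell from E18 to P4 and 1 rose (median log2 -0.61), and the embryonic globin gene Hba-x was at least 6.04-fold lower. In the immediate early list 10 of 17 genes rose and none fell (median log2 0.30, limma adjusted p = 0.058 with an estimated correlation), with Klf4 up 5.04-fold and Nr4a1 4.61-fold. Among contractile genes of vessels and pericytes Cnn1 rose 8.32-fold and Acta2 2.45-fold, and Mal, of myelinating cells, rose 4.92-fold. These are single members, and the medians (log2) were 0.22 for pericytes and smooth muscle and 0.52 for Schwann cells and nerve.

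From P10 to 4W 14 of 15 glycogen genes rose and 1 fell (median log2 0.96, limma adjusted p = 0.060 with an estimated correlation), with Gys2, a glycogen synthase, up 13.5-fold and Pygl, a phosphorylase, 11.2-fold. In the complement and acute phase list 11 of 13 genes rose (median log2 1.18), with Hp, the haptoglobin gene, up 10.3-fold. Adrb3, the receptor through which noradrenaline activates fat cells, rose 5.35-fold and the chemokine gene Cxcl14 20.7-fold. From 4W to 8W the immediate early genes Egr1 and Fos rose 8.01-fold and 3.35-fold, and the clock gene Per2 fell 5.63-fold. In the clock list 10 of 18 genes fell and 3 rose (median log2 -0.52, limma adjusted p = 0.10 with an estimated correlation). The time of day of sampling is not given in the sources used here.

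The pairs 4W and E18, and 8W and P4, hold no P10 array, and their muscle medians differ by less than those of every neighbouring pair of ages except P10 and 4W. Age and slide are mixed in both pairs, and no slide term was fitted for them. E18 lies on slide 1 and 4W on slide 2. The 8W arrays lie on slide 2, where P4 has only its replicate 1. Between E18 and 4W 10655 genes changed by limma (4954 up and 5701 down), and between P4 and 8W 11050 (5486 up and 5564 down). In these 2 comparisons cell division genes fell (median log2 -3.38 and -3.99), as did imprinted growth genes (-2.77 and -2.98) and matrix genes (-1.39 and -2.38). Antigen presentation genes rose (2.00 and 2.28), as did fat synthesis genes (1.099 and 2.46) and genes of branched-chain amino acid breakdown (0.45 and 0.91). The skeletal muscle median was 0.92 and -1.57 in the same comparisons, and that of developing skeletal muscle -1.50 and -0.16. Neither pair is therefore matched in muscle genes. Of 16822 probes without a gene symbol, 9835 passed the F test.

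Other splits of the arrays were counted with the arrays of the compared ages alone. For P4 versus E18 only 1 of 35 splits, the real one, reached its 9383 genes, the highest other giving 8. For P10 versus P4 only 1 of 35 reached 7977, the highest other giving 3. A random labelling of these arrays can therefore be excluded for both. For the F test 1 of 100 groupings, the real one, reached 13830 genes, the highest other giving 2648, so a random labelling can be excluded there too. The labels do not say whether the arrays of an age are separate animals. The splits therefore cannot exclude chance differences between animals. For 4W versus P10, 8W versus 4W and 8W versus E18 the 10 splits are too few for a share under 0.05. The real values were 8295, 6314 and 12031 genes, and the highest other split gave 0 in each.

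The skeletal muscle markers fell to P4, rose to P10 and fell to 8W. Scaling between the arrays is argued against, since the change from 4W to 8W nearest to 0 under median or quantile scaling was -6.43. Under these 2 scalings the medians were -3.53 and -3.74 from E18 to P4, and 3.74 and 3.87 from P4 to P10. Carry-over that differs between these arrays of an age is argued against by the spread of the markers within an age, at most 1.33 times that of genes of equal level. The arrays may not be separate animals, so this cannot speak to carry-over that differs between animals. Only markers well above background on every array of the age entered: 16 at P4 and 8 at 8W, against 22 at E18, P10 and 4W. Muscle tissue in the samples, in an amount shared by the arrays of an age, may underlie the pattern: of 38 genes of another muscle list at least 81.6% moved by 2-fold or more with the markers in each of the 3 comparisons. That share lies between the bounds set beforehand, so dissection and a muscle-like program of the tissue at some ages cannot be told apart here.

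On all 3 P10 arrays Xist was well above background and Ddx3y was not, which argues against 1 mislabelled array. Xist was also well above background on 2 of 3 E18 arrays, at a far lower level (-3.24 and -2.51), with Ddx3y present. The Y-linked Uty, though, was well above background on P10 replicate 3 (-0.89), higher than on any other array, and Eif2s3y on P10 replicate 2 (-4.71). Xist lay at 1.023 to 1.096 on the P10 arrays and at -2.508 or lower on all others. Ddx3y lay at -6.491 or lower at P10 and at 2.12 or higher on all others. Eif2s3y lay at -4.71 or lower at P10 and at 2.387 or higher on the others with a value. For these genes the levels argue against male pups at P10, and female pups there with males at the other ages may underlie them. Uty was low on P10 replicates 1 and 2 (-6.684 and -6.345), but replicate 3 goes the other way. The labels give no sex. Of 11 genes that escape X inactivation 6 were higher at P10, with a median of 0.10 (log2) over the mean of P4 and 4W, between the bounds set beforehand. That median alone does not decide the sex of the P10 pups. The Xist and Ddx3y levels set all P10 arrays apart from those of the other ages. Sex and age therefore cannot be told apart for the comparisons with P10. Eif2s3x was lower there by -2.54, and its probe might share signal with Eif2s3y.

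Dio2 and Ppargc1a peaked at P4. A difference between the slides is argued against, since Dio2 rose by 3.20 and Ppargc1a by 3.19 (log2) within slide 1. An acute cyclic AMP response when the tissue was taken, such as one to cold or handling, may contribute: 27 other response genes had a median of 0.63 for P4 minus E18 and of 0.35 for P4 minus P10. The lower value falls between the bounds set beforehand, so an acute response and a developmental program of this age cannot be told apart.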
